A study of Drosophila melanogaster with 3 samples.

How the data were processed

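ChIP-seq was performed on whole, mixed-sex embryos of 0 to 24 hours from a fly line with an eGFP exon inserted into dpn. Per the labels, chromatin was sheared by sonication to 200 to 800 bp and precipitated with an antibody against GFP, while the antibody field of the labels names dpn. The 3 libraries are 3 biological replicates of 1 group. The labels name a possible control experiment, and the deposited lists of files name a control alignment as a parent of each peak list. No control library is among the samples.

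The authors deposited peak lists without header lines for the dm6 and the dm3 genome. Per the deposited lists of files, peaks and background regions were called on each replicate and on the pooled replicates, each against a control alignment, and served as input for the IDR procedure, which compares the ranks of peaks between replicates. The aligner, the peak caller and their versions are not stated in the sources used here. Column 7 of the deposited lists is the peak caller's signal value per region, which was used only to rank entries within a list and never compared between lists. Column 9 is, per the format of the deposited lists, the −log10 of a q-value. It had the same value for all entries of the IDR-thresholded list (4.05 in dm6 and 4.04 in dm3), so it did not rank them. Column 10 of the deposited lists, of a unit other than a signal, is the offset of the summit from the start of the region in bp. Each replicate list and each pooled list held 30000 entries, and the IDR-thresholded list 5164 in dm6 and 5175 in dm3. Most regions had a fixed width, 416 bp for 69.5% of the dm6 IDR-thresholded peaks. In 14 cases a peak of this list repeated the interval of another with a different summit, and such peaks were kept. Lists of this kind carry no read counts, so the depth per sample and the counting error of each peak are unknown.

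The dm6 lists were the main source. Their arm names and positions fitted genome release 6, for which the reference held the Ensembl annotation (release 115) and the NCBI sequence and annotation. Of 13934 genes with the same symbol in both annotations, 13933 had the same arm, start and end. No coordinate was converted between builds, and positions are given counted from 1.

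A replicate's top peaks are as many of its highest-ranked entries as the IDR-thresholded list holds. Peaks were matched when their summits lay within 150 bp, and chance levels came from 1000 random placements within the same arms (100 for the other list sizes of the pairwise overlap, which are not printed). Summits were assigned in order to promoter (within 500 bp of a start site of any gene), 5' UTR, coding exon, 3' UTR, non-coding exon, intron and intergenic sequence, and compared with 1000 random placements by a two-sided permutation test. Non-coding exons were added as a class after the annotation was seen. For hexamers, both strands were merged (2080 hexamers). The 50 bp on either side of the summit were compared with windows of the same length in the same peak's flanks, 400 bp away, by a two-sided exact binomial test on the peaks with the hexamer at one place only. Ratios are peaks with the hexamer only at the summit over peaks with it only in the flanks, each with 0.5 added. Ratios were also set beside those of hexamers with the same base composition on merged strands and the same number of CpG dinucleotides. Hexamers that span the summit position itself were left out so that both windows offered the same number of positions.

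A gene was called bound when a summit lay within 1000 bp of any of its start sites. The 25 lists were compared with all other protein-coding genes on the main arms by Fisher's exact test, two-sided. They were neuroblast, temporal series, proneural, Notch pathway, E(spl) complex bHLH, Bearded family, other Hes and Hey, sex determination, pair-rule and segment polarity, gap and maternal, Hox, neuron, glia, muscle, fat body, hemocyte, gut, trachea, epidermis, cell cycle, heat shock, germ line, ribosomal protein, chemoreceptor and cuticle protein genes. Of 309 symbols entered, 295 matched the annotation, 9 matched under an updated symbol and 5 matched none. The last 3 lists were made from symbol patterns. All p-values were adjusted by the Benjamini-Hochberg method within each family of tests, with a threshold of 0.05. Named genes were chosen by a rule. It took dpn, the genes nearest to the 15 strongest peaks, up to 3 bound genes with the strongest promoter peak in each list (1 for lists from symbol patterns) and all bHLH members of the E(spl) complex. Lists, tests, the rule and most alternatives were fixed before the data were examined.

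Alternatives changed the matching distance, the list sizes, the promoter window, the annotation, the sequence windows, the background, the assignment of peaks to genes and the peak set, and left out each replicate in turn by keeping the peaks matched in both others. The peaks kept when a replicate was left out still came from the IDR-thresholded list made with all 3 replicates. Odds ratios of gene lists under alternatives have 0.5 added to each of the 4 counts. For the dm3 lists, counts, overlaps and arm shares were compared, and no arm lengths or genes of that build were used. The procedures were tested on simulated data. With CACGTG planted at 5.00% of 5164 random positions, the hexamer test gave it the smallest p with a gain of 4.92 percentage points. There, 1 hexamer that does not overlap it passed the threshold. Random positions lack the higher A/T content that the summits have against their flanks, and the planted share exceeded that of CACGTG in the data. The simulation therefore gives neither the power nor the rate of false calls at the real summits. With 28 of 40 genes bound in 1 planted list among 25, the list test called that list and none of the 24 others, over 13945 genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.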

Results

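Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on whole fly embryos that express a fusion of Deadpan with the green fluorescent protein eGFP. Deadpan, the product of dpn, is a basic helix-loop-helix repressor of the Hes family, known for its part in neural stem cells (neuroblasts) and in counting X chromosomes during sex determination. The eGFP exon sits in an intron of dpn, and the precipitation used an antibody against GFP. Embryos of both sexes were collected over 0 to 24 hours, so that all stages of embryogenesis and all tissues were mixed. The series holds 1 group with 3 biological replicates and no library of another condition, so the comparisons below set the bound regions against the genome, against their own flanks and against other genes. Each replicate is represented by a ranked list of 30000 peaks and background regions. The number of reads behind each list is not given in the files used here, and the depth is therefore unknown.

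The first question was how many regions had a peak and how far the replicates named the same ones. On the dm6 genome the authors' list held 5164 peaks that passed the irreproducible discovery rate (IDR) threshold, and all 5164 were the strongest entries of the list made from the pooled replicates. The strongest peak, on chromosome 2L at 480836 to 481330, lay in an intron of ush, 1371 bp upstream of the nearest start site, that of cbt (FBgn0043364), a zinc finger transcription factor gene, and was ranked 1 in each of the 3 replicates. The next peaks lay 99 bp upstream of CG14100 (FBgn0036889, chromosome 3L, 19590402 to 19590837) and 43 bp upstream of Ugalt (FBgn0024994, chromosome X, 2703666 to 2704123), the gene of a UDP-galactose transporter. Peak 4 lay in an intron of CG11050 and peak 5 in an intron of px, 198 bp from an internal start site. Chro, which encodes the chromosomal protein Chromator, held peak 6 over its 5' UTR (FBgn0044324, chromosome 3L, 22878685 to 22879135). An intron of ph-p, a Polycomb group gene, held peak 7 (FBgn0004861, chromosome X, 2137128 to 2137606). Among the 15 strongest peaks, the others were nearest to Lk6, mRpL41, PNPase, CG4004, Tcs5, Atat, CG9663 and CG32772. For the 15 peaks, only start sites of protein-coding genes were considered. The summit assigned to CG4004 lay 5130 bp downstream of its start site, in a non-coding exon of lncRNA:Vinr. The 15 peaks kept high places in every replicate, the lowest single rank being 21, for the peak of Tcs5 in replicate 1.

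Among equally many top-ranked entries of a replicate, 85.3% ± 1.23 (SD, n = 3) of the 5164 peaks had a summit within 150 bp, against 1.16% for randomly placed positions (mean of 1000 placements per replicate; the highest single placement gave 1.72%). The values were 84.9%, 84.4% and 86.7% for replicates 1, 2 and 3. The 5164 peaks came from these same replicates, as the strongest entries of their pooled list down to the IDR threshold. A high recovery was therefore largely fixed in advance, and the random level is no test of agreement. For 3457 peaks (66.9%) a match was present in all 3 replicates, for 487 peaks in only 1, and for 40 peaks in none of them. Between pairs of replicates, 74.7% (1 and 2), 77.7% (1 and 3) and 76.2% (2 and 3) of the top 5164 entries matched, a mean of 76.2% ± 1.48 (SD, n = 3 pairs). The overlap was 84.8% ± 0.586 for the top 500 entries and 65.6% ± 3.05 for the top 10000 (SD, n = 3 pairs).

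The second question was where in the genome the peaks lay. Promoters took the largest share: 2864 of the 5164 summits (55.5%) lay within 500 bp of an annotated start site, 4.08 times the 13.6% of randomly placed positions. In the replicates' own top peaks the share was 55.5% ± 1.51 (SD, n = 3). Coding exons outside promoters were nearly empty, with 18 summits (0.349%) against 13.7% at random, and 3' UTRs held 0.775% against 4.44%. In the replicates' own top peaks the share of coding exons was 0.691% ± 0.580 (SD, n = 3), highest in replicate 2 (1.36%). Introns held 1582 summits (30.6%, against 39.5%) and intergenic sequence 592 (11.5%, against 27.2%). In a two-sided permutation test with 1000 placements on the same chromosome arms, promoters, coding exons, 3' UTRs, introns and intergenic sequence each gave p = 0.002, the smallest value these placements can give (adjusted p = 0.0028 over 7 classes). The 5' UTRs outside promoters (0.562% against 0.784%, adjusted permutation p = 0.0769) and non-coding exons (0.755% against 0.795%, adjusted p = 0.851) did not pass the test. Promoters were assigned first, so their high share by itself lowers the shares of all other classes. The tests of introns and intergenic sequence therefore do not show that summits outside promoters avoid them. Introns held 1582 of the 2300 summits more than 500 bp from a start site.

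**Figure D1:**
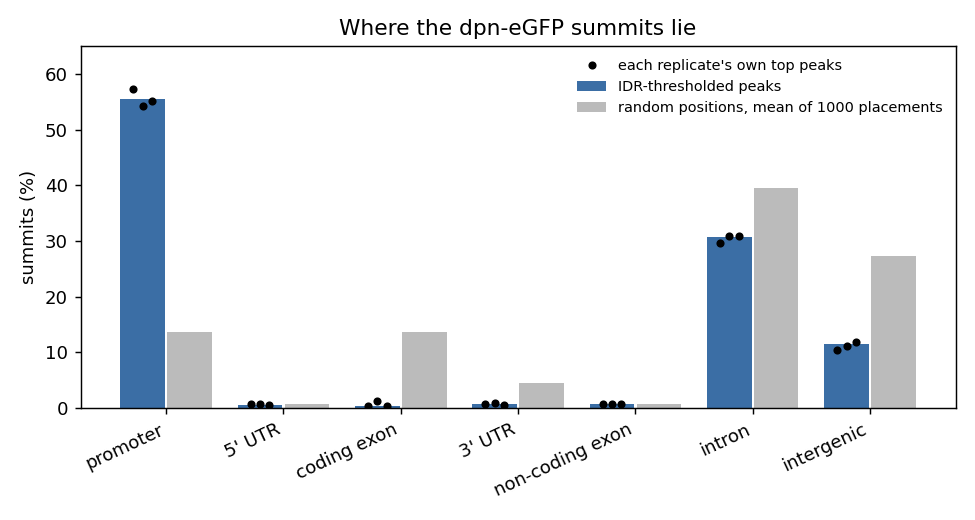
Share of summits (vertical axis, %) in 7 annotation classes (horizontal axis). Blue bars are the 5164 IDR-thresholded peaks, grey bars the mean of 1000 random placements on the same arms, and black points each replicate's own top peaks. Promoters hold 55.5% of the summits against 13.6% at random, and coding exons 0.349% against 13.7%.

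The promoter share followed the rank of the entry, in rank classes chosen after the lists were seen. It was 68.5% ± 1.67 among the top 500 entries of the replicates and 20.6% ± 0.761 among their 10000 lowest entries (SD, n = 3 replicates), which still lay above the share of random positions.

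Over the chromosome arms the peaks were spread nearly as sequence is. Chromosome 4, a small and largely heterochromatic chromosome, held 24 peaks (0.465%) and 1.01% of the sequence (exact binomial test, two-sided, adjusted p = 0.000117 over 6 arms). In the replicates' own top peaks its share was 0.484% ± 0.0887 (SD, n = 3). Against its share of protein-coding genes (0.574%) chromosome 4 did not stand apart (exact binomial test, adjusted p = 0.446). The X chromosome held 953 peaks (18.5%) and 17.6% of the sequence, which did not pass the exact binomial test (adjusted p = 0.199). Its share of peaks was above its share of protein-coding genes (15.7%; exact binomial test, adjusted p = 9.8e-07), while 2R held 18.3% of the peaks and 20.5% of the genes (adjusted p = 0.000383). The share of X was 18.3% ± 0.473 in the replicates' own top peaks (SD, n = 3). Among the peaks matched in both replicates 2 and 3, the X chromosome held 19.2% and also passed the test against sequence length. These peaks still came from the list made with all 3 replicates.

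The third question was which short sequences marked the summits. Hes proteins are known to bind the E-box forms CACGTG and CACGCG and the N-box CACNAG. Of the N-box forms, CACGAG, CACAAG and CACTAG were among the hexamers fixed in advance, and CACCAG was not. CACGTG lay within 50 bp of 41 summits (0.794%) and in the flanks of 63 peaks (1.22%), a ratio of 0.654 that did not pass the test (exact binomial test on peaks with the hexamer at one place only, two-sided, adjusted p = 0.0635 over 2080 hexamers). CACGCG was less frequent at summits than in flanks, 1.78% against 2.71% (ratio 0.653, adjusted exact p = 0.00412), as was the N-box form CACGAG, 1.74% against 2.48% (ratio 0.704, adjusted exact p = 0.0226). In each of the 3 replicates' own top peaks these hexamers had ratios below 1, with means of 0.731 ± 0.0538 for CACGTG, 0.636 ± 0.0911 for CACGCG and 0.686 ± 0.0288 for CACGAG (SD, n = 3). In settings chosen after seeing the data, CACGTG had an uncalled ratio of 1.22 in the 500 strongest peaks (1% of summits against 0.8% of flanks). In other such settings it passed as less frequent, in full-width peaks (0.515) and with a contiguous window across the summit (0.571). The call of CACGCG was lost in 5 of 18 alternatives, namely flanks at 800 bp (0.766), promoter-distal peaks (0.544), promoter peaks (0.698), the 500 strongest peaks (1) and random positions of the same annotation class (odds ratio 0.958). That of CACGAG was lost in 11 of 18 alternatives, among them flanks at 800 bp (ratio 0.778), the same random positions (odds ratio 0.759) and the peaks matched in both other replicates when replicate 1 was left out (ratio 0.694), all on the same side of 1. Other hexamers of the same base composition and number of CpG dinucleotides had similarly low ratios, with medians of 0.676 for the composition of CACGTG (51 hexamers), 0.616 for that of CACGCG (23) and 0.660 for that of CACGAG (47). Except for CACGTG, this comparison was added after seeing the data. The N-box form CACTAG was more frequent at summits, 3.21% against 1.45% (ratio 2.24, adjusted exact p = 3.09e-08), and its ratio was 2.13 ± 0.0715 in the replicates' own top peaks (SD, n = 3). The median for its composition was 0.989 (239 hexamers), and CACTAG stood at percentile 99.2. The highest ratio of that composition, 2.85, was that of ACACTG, which is not an N-box form. In the 500 strongest peaks alone, a set chosen after seeing the data, its ratio was 1.10 and the call was lost. CACAAG, CAGCTG, CATATG, CAGGTG and CACATG did not pass the test, with ratios from 0.819 for CAGGTG to 1.09 for CATATG. Of these, CAGGTG and CACATG were called less frequent with a window of 100 bp (ratios 0.755 and 0.780) and in replicate 1's own top peaks (0.766 and 0.722). CAGGTG was called so with flanks at 800 bp (0.633) and in replicate 3's own top peaks (0.748) too. CAGCTG was called less frequent in promoter-distal peaks (0.598), and CATATG was called more frequent against random positions of the same class (odds ratio 1.42).

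Of all 2080 hexamers, TATCGA gave the smallest p of those more frequent at summits. It is part of the element recognised by the promoter factor DREF, and it lay at 524 summits (10.1%) against 3.23% in the flanks (ratio 3.34, adjusted exact p = 1.42e-42). In the replicates' own top peaks 9.90% ± 0.871 of summits and 3.52% ± 0.186 of flanks held it (SD, n = 3). The A/T-only hexamers TTAAAA (25.6% against 14.5%), AAATAT (25.9% against 15.3%) and TTTAAA (16.2% against 7.94%) came next. Among the 10 hexamers with the smallest p and a higher share at summits were also CGATAG (7.82% against 2.40%) and ATCGAT (8.04% against 2.85%), which overlap TATCGA, and ACACTG (9.57% against 3.62%). The other 3 were ATTTAA, CTTAAA and AAAATA. In total 487 hexamers were more frequent and 751 less frequent at summits. CAGGTA, the core of the site of the early embryonic activator Zelda, did not pass the test (2.05% against 2.25%, adjusted exact p = 0.617), and GAGAGA, a site of GAGA factor, was less frequent (4.11% against 5.09%, adjusted exact p = 0.0312). The direction of GAGAGA turned with flanks at 800 bp (ratio 1.03) and against random positions of the same class (odds ratio 1.10), and its call was lost with a window of 100 bp (0.996) and in promoter peaks (0.892). The median for its composition was 0.794 (39 hexamers). Summit windows were richer in A and T (62.7%) than the left (56.5%) and right (56.6%) flanks. Among 16 hexamers of the composition of TATCGA the median ratio was 1.03. Their highest ratio, 2.98, was that of the overlapping ATCGAT. The enrichment of TATCGA did not pass the test in the 2300 peaks more than 500 bp from a start site (ratio 1.31, adjusted exact p = 0.224).

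**Figure D2:**
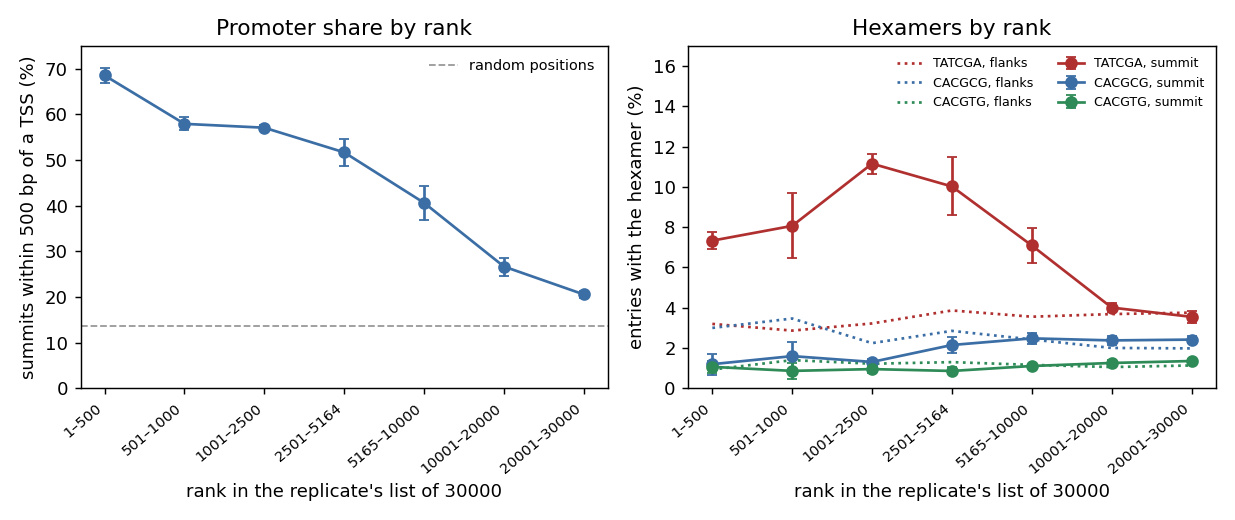
Left, share of summits within 500 bp of a start site (vertical axis, %) by rank in the replicates' lists (horizontal axis), and the share of random positions as a dashed line. Right, share of entries with TATCGA, CACGCG or CACGTG within 50 bp of the summit (points and solid lines) and in the flanks (dotted lines). Points and bars are the mean and SD of 3 replicates. The promoter share goes from 68.5% in the top 500 to 20.6% in the 10000 lowest entries, and TATCGA from 7.33% through 11.2% to 3.55%.

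The fourth question was which genes had a bound promoter, with a summit within 1000 bp of a start site. Such a peak was present at 3891 of 13945 protein-coding genes (27.9%). In the replicates' own top peaks the number was 3836 ± 85.4 (SD, n = 3). Of 25 gene lists, 3 were bound more often than other genes and 2 less often (Fisher's exact test, two-sided, adjusted over the 25 lists), and 20 did not pass the test. Each of the 5 lists that passed lay on the same side in the own top peaks of all 3 replicates. Genes are not independent replicates, and neighbouring genes can share a peak.

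Ribosomal protein genes stood highest. Of 82 such genes 68 (82.9%) were bound, against 27.6% of other genes (odds ratio 12.8, adjusted exact p = 8.58e-24), and the replicates' own top peaks gave 82.5% ± 2.54 (SD, n = 3). The strongest of these peaks lay 20 bp upstream of RpS27 (FBgn0039300, chromosome 3R, 25247360 to 25247725), which held rank 51 in the IDR list and ranks 36, 52 and 66 in replicates 1, 2 and 3. Cell cycle genes were also bound more often, 17 of 26 (65.4%; odds ratio 4.90, adjusted exact p = 0.000469; 62.8% ± 8.01 in the replicates' own top peaks, SD, n = 3). They included the replication licensing gene dup (rank 593) and the mitotic kinase genes aurA (rank 890) and polo (rank 1073). Without replicate 3 the number was 12 of the 26 and the call was kept (odds ratio 3.01, against 4.78 in the main setting, each with 0.5 added to the counts). With the stronger part of the list alone, 7 of the 26 were bound and the call was lost (odds ratio 1.98). Of the 26 genes, 13 had a start site within 1000 bp of that of another gene. When these were left out, 7 of 13 were bound and the call was kept (odds ratio 6.01).

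Genes of the Notch pathway were bound in 13 of 18 cases (72.2%; odds ratio 6.74, adjusted exact p = 0.000592; 70.4% ± 6.42 in the replicates' own top peaks, SD, n = 3). The strongest peak of this group lay in an intron of gro, the gene of the co-repressor Groucho that Hes proteins recruit (FBgn0001139, chromosome 3R, 26042358 to 26042650), 125 bp upstream of an internal start site, with rank 135 in the IDR list and ranks 158, 133 and 132 in the replicates. Nct (rank 409) and aph-1 (rank 442), which encode subunits of the gamma-secretase complex, followed. The summit of Nct lay 994 bp upstream of its start site, near the edge of the window. Notch itself, N, was bound with rank 2003 and Su(H), the gene of the transcription factor of the pathway, with rank 2430. Delta, Ser, H, mib1 and spdo were not bound. N, Su(H) and these 5 genes were named after their values were seen. Of the 18 genes, 10 had a start site within 1000 bp of that of another gene. Without such genes 3 of 8 were bound and the call was lost (odds ratio 3.30), as it was with a window of 5000 bp around the start site (odds ratio 2.65), and with a window of 500 bp the odds ratio was 3.82 with the call kept.

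The E(spl) complex on chromosome 3R encodes, among others, Hes proteins that respond to Notch signalling, and 3 of its 7 bHLH genes were bound (42.9%, adjusted p = 0.599 by Fisher's exact test; 47.6% ± 16.5 in the replicates' own top peaks, SD, n = 3). A summit lay 512 bp upstream of E(spl)m3-HLH (FBgn0002609, 26021196 to 26021329, rank 661), 310 bp upstream of E(spl)m7-HLH (FBgn0002633, 26036520 to 26036935, rank 2074) and 44 bp into E(spl)mbeta-HLH (FBgn0002733, 26005771 to 26006186, rank 4638). Ranks in replicates 1, 2 and 3 were 698, 674 and 576 for E(spl)m3-HLH, 2370, 4234 and 1481 for E(spl)m7-HLH, and 3742, 7682 and 4123 for E(spl)mbeta-HLH. The remaining bHLH genes of the complex had entries in the pooled list below the IDR threshold, at rank 5798 for E(spl)mdelta-HLH, 7239 for E(spl)m8-HLH, 9949 for E(spl)mgamma-HLH and 12115 for E(spl)m5-HLH. None of the 8 Bearded family genes, 4 of which lie in the complex, and none of the 5 other Hes and Hey genes was bound (adjusted exact p = 0.322 and 0.552).

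The dpn gene (FBgn0010109, chromosome 2R, 8228971 to 8232330, minus strand) had no IDR-thresholded peak within 1000 bp of its start site. The pooled list held an entry 32 bp upstream of the start site, at 8232154 to 8232569, with rank 14836. This entry had rank 24684 in replicate 2 and 7994 in replicate 3, and replicate 1 listed none within 150 bp. The strongest entry within 6000 bp, looked up after the values were seen, lay 5126 bp upstream at 8237248 to 8237663, over the 5' UTR of the neighbouring gene pnut, with rank 2098 and ranks 3065, 1806 and 1632 in the replicates.

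Lists of neural development did not pass the test. Neuroblast genes were bound in 4 of 21 cases (19.0%, adjusted exact p = 0.653), among them the growth regulator gene brat (chromosome 2L, 19164989 to 19165318, rank 170), numb (rank 579) and pros (rank 3764), which are known for the asymmetric division of neuroblasts. The temporal series of neuroblasts had 3 of 16 bound genes (18.8%, adjusted exact p = 0.725). They were ey (rank 2312), dan (rank 3625, in an intron of lobo) and hb (rank 4632). The proneural list, which also holds da and emc, had 2 of 11 bound (18.2%, adjusted exact p = 0.839). These were da (rank 1913) and emc (rank 2326) themselves. The members ac, sc, l(1)sc, ase, ato, amos and cato, named after their values were seen, were not bound. Neuron genes stood at 4 of 19 (21.1%, adjusted exact p = 0.733). Their strongest peaks lay at elav (rank 122, in an intron of the neighbouring gene arg), Fas2 (rank 2756) and Syx1A (rank 2994, in an intron of eIF4EHP). Glia genes stood at 5 of 11 (45.5%, adjusted exact p = 0.382), with moody (rank 95, in an intron of CG4313), Gs2 (rank 400) and Gli (rank 2149).

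In sex determination, 9 of 18 genes were bound (adjusted exact p = 0.216; 48.1% ± 8.49 in the replicates' own top peaks, SD, n = 3). They included gro, the splicing regulator gene fl(2)d (rank 902) and Sxl, the master switch of female development, whose summit lay in an intron, 340 bp downstream of a start site (FBgn0264270, chromosome X, 7096518 to 7096933, rank 1087, ranks 895, 1225 and 1252 in the replicates).

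Chemoreceptor genes and genes of cuticle proteins were rarely bound. Of 179 chemoreceptor genes 5 were bound (2.79%, odds ratio 0.0731, adjusted exact p = 8.31e-18; 2.98% ± 1.29 in the replicates' own top peaks, SD, n = 3), with the strongest peak 740 bp upstream of Or88a (rank 1393). Of 102 cuticle protein genes 1 was bound, Cpr73D (rank 3289; 0.980%, odds ratio 0.0253, adjusted exact p = 1.31e-12), and each replicate gave the same share.

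Patterning genes and the markers of other tissues did not pass the test. Pair-rule and segment polarity genes had 1 of 16 bound, ptc (rank 3270, adjusted exact p = 0.216). Gap and maternal genes had 3 of 13 (adjusted exact p = 1), bcd (rank 1032), nanos (rank 1308) and hb. The summit counted for nanos lay over the 5' UTR of CG11779. None of the 8 Hox genes was bound (adjusted exact p = 0.322), while the list passed the test in the opposite direction when each peak went to its nearest start site (odds ratio 7.54). Muscle genes had 6 of 21 bound (adjusted exact p = 1), with sls (rank 433), rols (rank 1562) and tin (rank 2563). Germ line genes had 5 of 11 (adjusted exact p = 0.382), with bgcn (rank 375). With a window of 5000 bp, 10 of the 11 were bound and the list passed the test (odds ratio 7.56). Heat shock genes had 5 of 13 (adjusted exact p = 0.578), with Hsp27 (rank 221), Hsp83 (rank 301) and Hsp26 (rank 536). Epidermis stood at 3 of 12 with tsl, rtv and shg (adjusted exact p = 1), fat body at 2 of 12 with apolpp and DNaseII (adjusted exact p = 0.696), and hemocytes at 1 of 14 with ush (adjusted exact p = 0.329). Gut had 1 of 11 with fkh (rank 482, adjusted exact p = 0.552) and trachea 1 of 12 with ttk (rank 4762, adjusted exact p = 0.382).

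**Figure D3:**
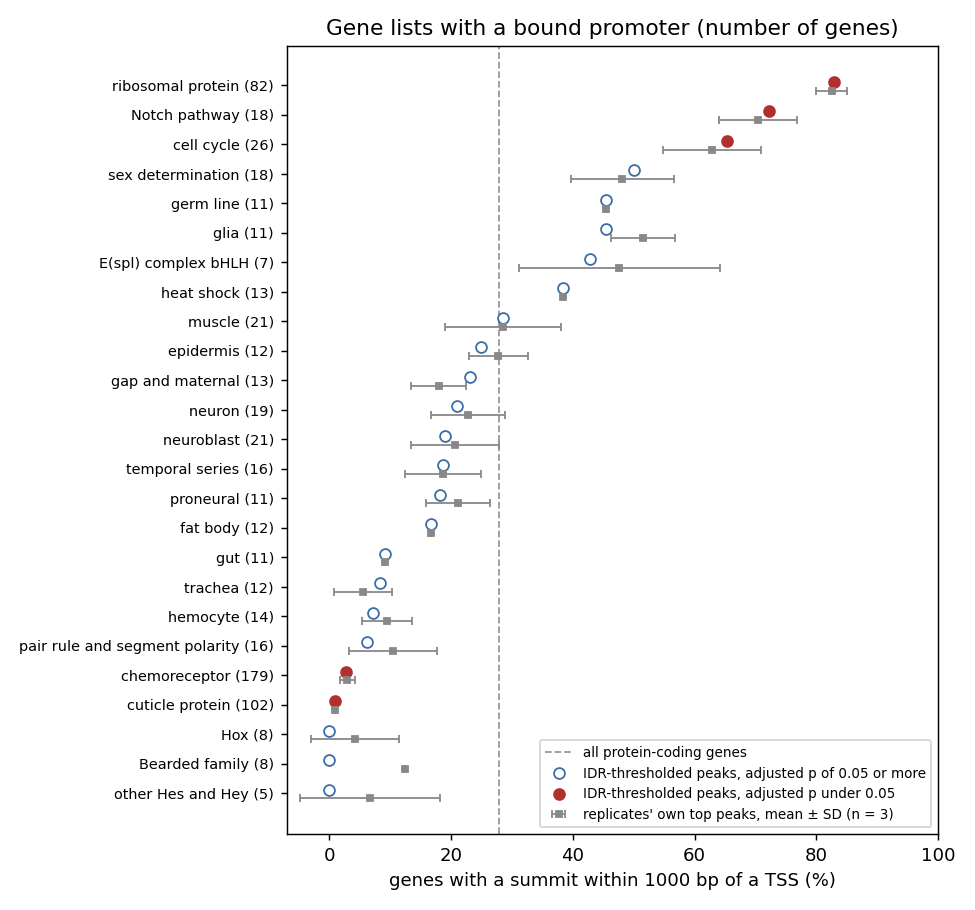
Share of genes with a summit within 1000 bp of a start site (horizontal axis, %) in the 25 gene lists (vertical axis, number of genes in parentheses). Filled red circles are lists with adjusted p under 0.05 and open circles the other lists, grey squares and bars the mean and SD of 3 replicates' own top peaks, and the dashed line all protein-coding genes (27.9%). Ribosomal protein genes (82.9%), Notch pathway genes (72.2%) and cell cycle genes (65.4%) lie to the right, chemoreceptor (2.79%) and cuticle protein genes (0.980%) to the left.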

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

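Both results below come from entries outside the IDR-thresholded dm6 list, on which the tests of the report rest, and they are given as values only. Some entries of the first set are named in the report by their rank. The group holds 3 samples, too few for a test of single samples that stand apart.

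The pooled list continued to lie at promoters below the IDR threshold: of the 4836 entries between the last IDR-thresholded peak and rank 10000, 43.0% had a summit within 500 bp of a start site, against 13.6% of random positions. On the dm3 genome the pooled list held 56 entries on heterochromatic or unplaced sequences, the highest of them at rank 5657, and the IDR-thresholded list held 0.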

How the results depend on the processing

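No paired analysis was possible because the series holds 1 group. Of 635 alternative values for 45 results, 577 kept their call, moved by less than the spread or, for counts, stayed within 1.5 times the main count, 28 lost a call, 13 gained one, 13 moved and 4 lay in the opposite direction. Of these 4, CACGTG in the 500 strongest peaks was uncalled in both settings. Among the 577 were 62 other comparisons uncalled in both settings whose ratio lay on the other side of 1. For the hexamers the 500 strongest peaks, and in all cases the alternatives with full-width peaks, a contiguous window, neighbouring peaks, shared start sites or the lowest entries as background were chosen after seeing the data. The number of peaks was 3457 with a match in all 3 replicates and 3781 to 3909 when a replicate was left out, and 2582 by construction in the stronger part of the list. Recovery in the replicates was 87.2% with a 1 bp overlap, 75.5% with summits within 50 bp, 98.9% in whole lists and 90.5% for the top 1000. Pairwise overlap was 79.6% with 1 bp, 59.7% within 50 bp, 84.8%, 84.3% and 65.6% for the top 500, 1000 and 10000, and 74.7% to 77.7% when a replicate was left out. The promoter share kept its call under each of its alternatives.

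For CACGTG the ratio was 1.22 in the 500 strongest peaks, uncalled and from 1% of summits against 0.8% of flanks. The hexamer became less frequent past the threshold in full-width peaks (0.515) and with a contiguous window across the summit (0.571). CACGCG lost its call with flanks at 800 bp (0.766), against random positions of the same class (0.958), and in the promoter-distal (0.544), promoter (0.698) and 500 strongest (1) sets. CACGAG lost its call in 11 of 18 alternatives and GAGAGA in 7, turning to 1.03 with flanks at 800 bp and to 1.10 against random positions. Notch pathway genes lost their call with a window of 5000 bp (odds ratio 2.65), with gene bodies (2.73) and without shared start sites (3.30), and cell cycle genes with the stronger part of the list (1.98), while their odds ratio was 3.01 to 4.01 when a replicate was left out. Germ line genes passed the test with a window of 5000 bp (7.56), and Hox genes rose to an odds ratio of 7.54 under the nearest start site, which assigns peaks at any distance. Arms past the threshold were 2 against gene shares and 1 to 2 when a replicate was left out. The cause of these changes was not tested. Without read depth, the peaks that a deeper library would add could not be estimated. The dm3 list gave no arm test.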

Other observations

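The gene families, the 8-base sequences, the comparison of the 500 strongest peaks and the use of matched lists as a test of an explanation were chosen after the main results were seen. Other families of broadly used genes were bound to different degrees. Mitochondrial ribosomal protein genes stood at 41 of 73 (56.2%, odds ratio 3.34, adjusted p = 2.56e-06 by Fisher's exact test over 9 families), proteasome genes at 19 of 32 (59.4%, odds ratio 3.79, adjusted p = 0.000389) and translation initiation factor genes at 19 of 44 (43.2%, odds ratio 1.97, adjusted p = 0.0427). The call of the initiation factor genes was lost against random lists matched on start sites and locus length, and those of the other 2 families were not. For the initiation factor genes the adjusted p was 0.0663 in this simulation, which drew genes with replacement. Aminoacyl-tRNA synthetase genes (13 of 31, adjusted exact p = 0.12) and genes of respiratory complex I (12 of 40, adjusted exact p = 0.727) did not pass the test. Families with restricted expression were bound less often: cytochrome P450 genes at 5 of 85 (adjusted exact p = 2.56e-06), odorant binding protein genes at 2 of 51 (adjusted exact p = 7.42e-05) and accessory gland protein genes at 2 of 47 (adjusted exact p = 0.000129). Jonah serine protease genes, 1 of 16, did not pass the test (adjusted exact p = 0.0696).

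ATCGATAG was present only at the summit in 175 peaks and only in the flanks in 17 (exact binomial test, adjusted p = 1.03e-29 over 32889 sequences of 8 bases), and TATCGATA, the core of the DREF element, in 159 and 16. The 20 sequences with the smallest p also held CAACACTG (130 and 11), AGCCCTGG (57 and 0), GGTCACAC (94 and 17), part of the core promoter element known as Motif 1, and 4 made of A and T only, TTTAAAAA (255 and 89), ATTTTTAA, ATTTAAAA and TATTTAAA.

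CACGTG was not more frequent at summits than in flanks, although Hes proteins are known to bind it. A/T-rich summits could mask an enrichment. Among 51 hexamers of the same base composition CACGTG stood at percentile 43.1. The exact 95% interval of its ratio, 0.428 to 0.980, ended below the 95th percentile of those hexamers, 1.32. This argued against a masked enrichment large enough to pass that percentile. The interval also reached above their median of 0.676, so a smaller masked enrichment stayed open. An enrichment restricted to promoter-distal peaks stayed open, since their ratio of 0.756 had an exact 95% interval of 0.357 to 1.54. One restricted to the strongest peaks stayed open too: 5 of the 500 strongest (1%, exact 95% interval 0.325 to 2.32) held CACGTG, against 1.43% of the 10000 lowest entries. No biological explanation was tested, because the series holds 1 group.

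Ribosomal protein genes were bound in 68 of 82 cases. Compact loci with several start sites did not account for this. The 10000 lists matched on start sites and locus length held a mean of 27.2 bound genes (central 95%, 19 to 35). These lists were not matched on nearness to another gene's start site. Of the 82 genes, 52 had a start site within 1000 bp of another gene's. Without them 21 of 30 were bound (70%) and the call was kept (odds ratio 11.9). A candidate explanation is signal at promoters of broadly used genes in general, whichever protein is precipitated. With 3 of the 5 broadly used families above other genes, fewer than the 4 set for this explanation before the test and more than the 1 that would have argued against it, this was left open. One of these 3 calls, that of the initiation factor genes, was lost against matched lists. Lists from a control precipitation were not used here, and no biological explanation was tested.

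TATCGA was the hexamer with the smallest p at the summits. The sequence of an average fly promoter was argued against as the whole cause. Of promoter peaks 15.6% held it, and of random promoters at the same distance 7.12% (odds ratio 2.42, Fisher's exact test, p = 1.65e-24). The random promoters held 57.5% A and T, against 61.0% at promoter peaks. The test therefore cannot exclude the sequence of the particular promoters that held peaks. A single replicate carrying the pattern was argued against as well, since TATCGA passed the threshold in the own top peaks of all 3 replicates. The peaks had been called against a control alignment, but no peak list of a control precipitation was used here. Whether the fusion protein itself or open chromatin at such promoters gives the signal stayed open, and no biological explanation was tested.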
